A study of Mus musculus with 6 samples.

How the data were processed

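RNA was extracted from formalin-fixed, paraffin-embedded primary tumours of mice with 4NQO-induced oral squamous cell carcinoma, per the labels' protocols. The labels name 3 vehicle samples and 3 samples given agonistic anti-CD40, numbered 1 to 3 in each group. They do not say that the samples came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

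The authors deposited 1 table of log2 normalized counts, as its name calls them, with 784 rows. By their row names, 770 are genes, 6 are positive controls and 8 are negative controls. Its 6 value columns carry the names that the labels give the 6 samples, and no other sample column was present. Control rows of this kind are typical of direct digital counting with colour-coded probes, but the platform, the counting software, the normalization and the quality filters are not given in the sources used here. The values themselves showed that each deposited log2 value is the logarithm of a library factor times a whole count plus an offset of 4.55 common to all libraries. All 4704 values came out whole within 0.05 of a count. The factors lay between 1.72 and 3.28, background had not been subtracted, and the mean of the 20 housekeeping genes was between 11.01 and 11.11 in every library, while the exact rule behind the factors was not identified. With an offset added before the logarithm, differences of genes with few counts are understated by that step. Counts near background are also multiplied by unequal factors, so such genes can differ between libraries through scaling alone.

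Recovered counts over the 770 genes summed to 578598, 357258 and 488585 in vehicle replicates 1, 2 and 3 and to 497475, 445159 and 333400 in anti-CD40 replicates 1, 2 and 3. A gene was taken as above background in a library when its count exceeded the mean of the 8 negative controls plus 2 SD, which lay at 24.7 to 26.6 counts. On the log2 scale this limit ran from 5.57 in vehicle 3 to 6.52 in vehicle 2. By this measure 523 genes were above background in all libraries, 618 in at least 3 and 82 in none. Library medians ranged from 7.68 to 8.19 log2, and correlations between libraries across genes from 0.920 to 0.974. Counts of replicate pairs differed by far more than counting noise, with a chi-square per degree of freedom of 64.2 to 121, so no library was counted as a duplicate. Symbols were compared with a RefSeq gene table of assembly GRCm38.p6, used only for names: 754 were current, 8 were synonyms, 2 matched once case was ignored and 6 did not match, and the symbols are given as the table has them. Ptgdr2 and Gpr44 stand in separate rows although they are synonyms of 1 gene. The table names no genome build, so no coordinates are given.

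Computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 for the plots. The groups were compared with limma (lmFit and eBayes, without trend, not robust) on the deposited log2 values of all 770 genes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 4 residual degrees of freedom and 3.37 prior degrees of freedom. An exact permutation test of 3 against 3 cannot give a p under 0.1. Negative binomial models were not fitted. The main fit used the deposited log2 values, and the counts recovered from them were fitted only with limma-voom. On simulated data for this comparison, with 770 genes, independent noise and 20 simulations, the procedure recovered 56.9% of genes changed by 2-fold, 90.7% of those changed by 4-fold and 96.4% of those changed by 8-fold, and 4.04% of the calls were false. Each simulation changed many genes at once, which eases the adjusted threshold. These shares do not carry over to a table in which few genes change. The list test was run on separate simulated tables with the same noise, in which only the complement list was shifted, by 0.5 log2. That list was called in 12 of 20, and 4 lists were called falsely in all. The noise was independent between genes, whereas the estimated correlation within the complement list was 0.16 in these data. The list counts may therefore be too favourable and do not carry over either.

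Gene lists were fixed before the data were examined: 29 lists of immune cell types, pathways, stroma, epithelium, proliferation and housekeeping genes. The 27 lists with at least 3 measured genes were tested with fry, which asks whether the genes of a list move on balance in one direction, with Benjamini-Hochberg adjustment over the 27. The list of skeletal muscle, nerve and adipose genes and that of hypoxia and glycolysis had 2 measured genes each and were not tested. The lists share members: 485 places hold 444 different genes. Camera, which compares a list with the other genes, was run with a preset correlation of 0.01 and with an estimated correlation.

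The rule for named genes was fixed at the same time. It takes Cd40, then up to 10 genes per direction past the adjusted threshold. Places left are filled by the genes of lowest unadjusted p under 0.05 whose groups do not overlap, among genes at or above the 25th percentile of mean level (6.25 log2). From each list it takes the 3 members of lowest p at any level, of which the text gives a selection. Genes named outside the rule are said to be so.

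Alternatives fixed before the data were examined were the replicate number as a block, a filter at the 25th percentile of level, a pseudocount of 16, median centring, quantile normalization, centring on housekeeping genes, eBayes with trend and robust, sample weights, each replicate left out in turn, both forms of camera, and fry on lists without shared genes. Alternatives added after seeing the data were limma-voom on the recovered counts, a filter on genes above background in at least 3 libraries, subtraction of the mean negative control, scaling to equal totals, the mean of 8 marrow genes as a covariate, and leaving out the 3 libraries with high granule genes. The marker sets of other cell sources (granule, B cell precursor, mature neutrophil, B cell, gland and platelet genes) were written after principal components of these libraries had been seen. A first fit of the comparison had also been examined before those alternatives were added. Groups of 3 were not tested for outlying samples.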

Results

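The data came from mice with oral squamous cell carcinoma induced by 4NQO, a chemical carcinogen. Tumours of animals given vehicle were set against tumours of animals given an agonistic antibody to CD40, a receptor of the tumour necrosis factor receptor family carried by antigen-presenting cells. Expression of 770 genes, mostly of immune function, was measured in 3 vehicle and 3 anti-CD40 samples of RNA from formalin-fixed primary tumours. The whole counts recovered from the deposited values summed to between 333400 and 578598 per library over these genes. Between 548 and 649 genes per library lay above the background set by the negative controls, 523 did so in all 6 libraries and 82 in none. Values below are log2 normalized counts, given as mean ± SD with n = 3 per group, and differences are anti-CD40 minus vehicle.

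The comparison addressed how gene expression in these tumours differs after agonistic anti-CD40. C5ar1, the receptor for the complement fragment C5a, was 7.73 ± 0.25 in vehicle and 8.82 ± 0.12 in anti-CD40 tumours, a difference of 1.09 (SE 0.23). Complement genes as a group lay higher in anti-CD40 tumours, 27 of 31 in the mean, by 0.43 for the list and 0.28 without vehicle 3. Birc5, which encodes the apoptosis inhibitor survivin, was 8.82 ± 0.09 in vehicle and 7.82 ± 0.39 in anti-CD40 tumours, and 14 of 20 interferon gamma response genes lay lower in the mean, by −0.44 for the list and −0.19 without vehicle 1. None of these differences passed the test: limma called 0 of 770 genes at an adjusted p of 0.05 (lowest 0.974) and 25 at an unadjusted p under 0.05, where chance gives 38.5, and fry called 0 of 27 gene lists. Limma-voom on the recovered counts likewise called 0 genes, with 26 at an unadjusted p under 0.05.

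Cd40, the target of the antibody, was 6.98 ± 0.42 in vehicle and 6.73 ± 0.49 in anti-CD40 tumours, and above background in 5 of 6 libraries. The difference of −0.25 had a 95% confidence interval from −1.05 to 0.54, and it was 0.028 without anti-CD40 3, −0.063 without vehicle 1, −0.48 without vehicle 3 and −0.44 without anti-CD40 2. Of the 20 measured genes of CD40 signalling and antigen-presenting cell activation, 9 were higher and 11 lower, by −0.093 in the mean and 0.0036 without vehicle 1 (fry adjusted p = 0.89). The members of lowest p were Tnfaip3, an inhibitor of NF-κB signalling (8.57 ± 0.26 and 7.95 ± 0.53), the NF-κB subunit gene Rel (8.92 ± 0.31 and 8.37 ± 0.36) and the costimulatory ligand gene Cd80 (7.63 ± 0.18 and 7.15 ± 0.76). Tnfaip3 differed by −0.63, but by −0.37 without anti-CD40 3, and Cd80 by −0.48, but by −0.11 without anti-CD40 1 and −0.87 without anti-CD40 2. The first value in each such pair is the vehicle group's.

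Among genes at or above the 25th percentile of mean level whose groups did not overlap, those of lowest p with higher means in anti-CD40 tumours were C5ar1 and 9 others. The CC chemokine genes Ccl9 (10.16 ± 0.57 and 11.37 ± 0.41) and Ccl6 (8.59 ± 0.51 and 9.44 ± 0.31) differed by 1.21 and 0.85. Irak3, a negative regulator of Toll-like receptor signalling, differed by 0.62 (SE 0.21), and the chemerin receptor gene Cmklr1 by 0.83 (SE 0.29). Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages, was 8.18 ± 0.19 and 9.06 ± 0.44. The remaining genes named by the rule were Creb5 (0.66), Tnfsf13, which encodes the cytokine APRIL (0.65), the sialic acid hydroxylase gene Cmah (0.94, 0.56 without vehicle 3) and the integrin gene Itga5 (0.60). Each of these 10 genes, C5ar1 included, had an adjusted p of 0.974 with limma.

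By the same rule, 6 genes with lower means in anti-CD40 tumours were named, Birc5 among them. Ccl20, which encodes the ligand of Ccr6, was 7.98 ± 0.29 and 6.63 ± 0.73, a difference of −1.35 (SE 0.39). Cd274, which encodes the checkpoint ligand PD-L1, was 8.88 ± 0.60 and 7.86 ± 0.48, a difference of −1.03 (SE 0.38) that was −0.68 without vehicle 1. The T cell surface gene Cd5 was 8.61 ± 0.20 and 7.78 ± 0.21. Ccl22, which encodes a ligand of Ccr4, differed by −0.59 (SE 0.25) and Klrk1, which encodes the activating receptor NKG2D, by −0.56 (SE 0.24). These genes and Birc5 again had an adjusted p of 0.974. Over all genes, 79 showed groups that did not overlap, 52 of them higher and 27 lower, which is 10.3% against the 10% that chance gives for 3 against 3.

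**Figure D1:**
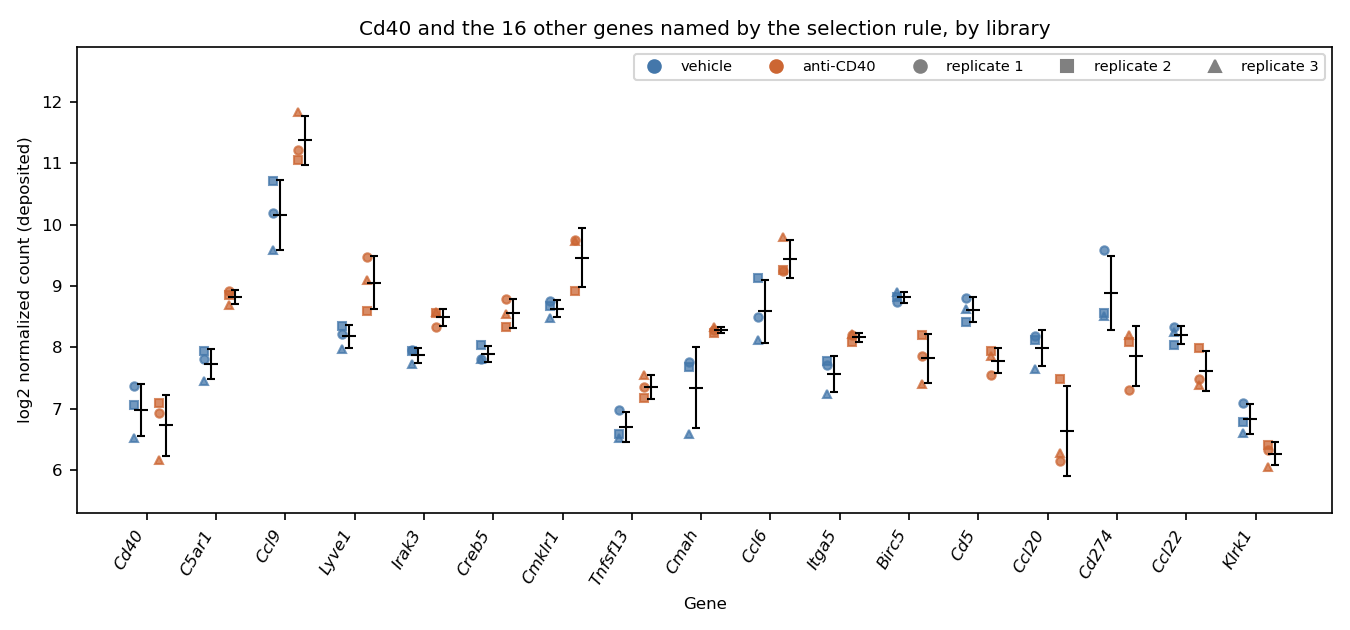
Log2 normalized counts (vertical axis) of Cd40 and the 16 other genes named by the rule, by gene (horizontal axis). Blue points are the 3 vehicle and orange points the 3 anti-CD40 libraries, the point's shape gives the replicate number, and black bars are the mean ± SD. Groups that do not overlap were a condition for choosing the 16, and no gene passed the adjusted threshold.

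Of 31 measured complement genes, 27 were higher and 4 lower in the mean, with a mean difference of 0.43 that was 0.28 without vehicle 3. The list's mean was 8.18, 8.30 and 7.78 in the 3 vehicle libraries and 8.56, 8.61 and 8.38 in the 3 anti-CD40 libraries. After C5ar1, the members of lowest p were the lectin pathway protease gene Masp2 (4.98 ± 0.41 and 5.76 ± 0.12), at or below background in every library, and complement factor I, Cfi (5.39 ± 0.37 and 6.47 ± 0.95, a difference of 1.09 that was 0.61 without anti-CD40 2), above background in 2 of 6. Fry gave the list an adjusted p of 0.695. Camera called it at a preset correlation of 0.01 (adjusted p = 3.88e-05) and not with an estimated correlation (adjusted p = 0.793). C5ar1 had an adjusted p of 0.0544 when adjusted over the list alone.

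Stromal and vascular lists also had more members higher than lower in anti-CD40 tumours. Of 16 fibroblast and extracellular matrix genes, 14 were higher, with a mean difference of 0.22 that was 0.11 without vehicle 3. They included the collagen genes Col3a1 (13.71 ± 0.20 and 14.14 ± 0.28, 0.43 apart but 0.29 without anti-CD40 2) and Col4a1 (10.72 ± 0.13 and 11.12 ± 0.18) and the transcription factor gene Snai1 (6.24 ± 0.23 and 6.83 ± 0.36). Of 20 endothelial and angiogenesis genes, 17 were higher, with a mean difference of 0.26 that was 0.11 without vehicle 3, 0.16 without anti-CD40 1 and 0.41 without anti-CD40 2. After Lyve1 came Vwf, von Willebrand factor (9.45 ± 0.31 and 9.94 ± 0.23), and Thbs1, thrombospondin 1 (10.20 ± 0.40 and 11.03 ± 1.04, 0.83 apart but 0.31 without anti-CD40 3 and 1.35 without anti-CD40 2). Of 9 mast cell and eosinophil genes, 8 were higher, by 0.36 in the mean, 0.69 without vehicle 2 and 0.12 without vehicle 3, with mast cell chymase Cma1 at 8.53 ± 0.37 and 9.14 ± 0.25. Only 3 of the 9, Cma1 among them, were above background in all 6 libraries. The list's mean was highest in the 3 libraries with high granule genes (below), at 7.15 in vehicle 2 and 7.04 and 6.93 in anti-CD40 1 and 2, beside 6.33, 6.01 and 6.62 in vehicle 1, vehicle 3 and anti-CD40 3. It holds 1 of those granule genes, Prg2. Fry's adjusted p was 0.695 for the fibroblast list and 0.89 for both others. Camera at the preset correlation called the fibroblast and endothelial lists, each with an adjusted p = 0.793 with an estimated correlation.

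Most genes of interferon response and antigen presentation lay lower in the mean, and without vehicle 1 each of the 5 lists below differed by less. Of 20 interferon gamma response genes, 14 were lower, with a mean difference of −0.44 that was −0.19 without vehicle 1. The list's mean was 8.92, 8.23 and 8.07 in vehicle libraries 1, 2 and 3, and 7.67, 8.17 and 8.05 in anti-CD40 libraries 1, 2 and 3. Lower members included Cd274, Ciita, the master regulator of MHC class II genes (7.73 ± 0.30 and 6.95 ± 0.56), and Irf1 (9.82 ± 0.56 and 9.12 ± 0.12). The T cell chemoattractant genes Cxcl9 (8.58 ± 1.43 and 7.23 ± 0.98) and Cxcl10 (8.82 ± 1.49 and 7.31 ± 1.23), picked after their values were seen, had overlapping groups. They differed by −1.35 and −1.51, but by −0.54 and −0.69 without vehicle 1 and −0.83 and −0.81 without anti-CD40 1. Of 34 type I interferon genes, 25 were lower (−0.21 in the mean, but 0.00060 without vehicle 1 and −0.46 without vehicle 3), with Stat2 at 9.46 ± 0.52 and 8.94 ± 0.04, Isg15 at 9.26 ± 1.06 and 8.46 ± 0.28 and Zbp1 at 8.32 ± 0.75 and 7.63 ± 0.59. Of 14 MHC class I and peptide processing genes, 12 were lower (−0.24), including the peptide transporter gene Tap1 (10.12 ± 0.75 and 9.24 ± 0.38), the immunoproteasome gene Psmb9 (9.46 ± 0.51 and 8.71 ± 0.40) and H2-K1 (12.73 ± 0.16 and 12.31 ± 0.32). That mean was −0.087 without vehicle 1, −0.36 without vehicle 3, −0.13 without anti-CD40 1 and −0.37 without anti-CD40 2. Of 11 MHC class II genes, 10 were lower (−0.28), with H2-Ab1 at 13.03 ± 0.55 and 12.63 ± 0.30. The list's mean was −0.051 without vehicle 1, −0.50 without vehicle 3 and −0.16 without anti-CD40 1. Of 15 dendritic cell genes, 13 were lower (−0.24, −0.13 without vehicle 2 and −0.40 without vehicle 3), with the cytokine receptor gene Flt3 at 6.60 ± 0.39 and 5.85 ± 0.34 (above background in 4 of 6 libraries), whereas Irf4 was 6.34 ± 0.21 and 6.94 ± 0.33. Without vehicle 1 the differences moved from −0.70 to −0.38 for Irf1, −0.52 to −0.24 for Stat2, −0.80 to −0.24 for Isg15, −0.69 to −0.27 for Zbp1, −0.88 to −0.45 for Tap1, −0.75 to −0.47 for Psmb9 and −0.39 to −0.080 for H2-Ab1. Without anti-CD40 1 they were −0.35 for Zbp1, −0.23 for H2-Ab1 and −0.27 for H2-K1 (−0.43 with all libraries), and Isg15 was −1.29 without vehicle 3. Fry gave each of these 5 lists an adjusted p of 0.89. Camera called all 5 at the preset correlation, and each had an adjusted p = 0.793 with an estimated correlation.

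Many lymphocyte genes lay near background: 6 of 17 T cell genes and 5 of 22 natural killer cell genes were above it in all 6 libraries. Of the 17 T cell genes, 14 were lower (−0.18 in the mean), among them Cd5 and Cd27 (5.39 ± 0.38 and 4.54 ± 0.48, at or below background in every library), whereas the costimulatory receptor gene Cd28 was 5.79 ± 0.35 and 6.27 ± 0.26 (above background in 3 of 6 libraries, 0.48 apart but 0.28 without vehicle 3). The list's mean was −0.039 without anti-CD40 1, −0.098 without vehicle 2, −0.10 without vehicle 1, −0.35 without vehicle 3 and −0.37 without anti-CD40 2. Camera called this list at the preset correlation, with an adjusted p = 0.793 with an estimated correlation, and fry did not (adjusted p = 0.89). By the same measure, 0 of 13 genes of CD8 T cells and cytotoxic effectors lay above background. In that list 6 were higher and 7 lower, with a mean difference of 0.04 that was −0.0016 after quantile normalization, and perforin, Prf1, at or below background in every library, was 4.60 ± 0.35 and 5.41 ± 0.72 (0.81 apart, 1.22 without anti-CD40 3). Of the 22 natural killer cell genes 13 were lower (−0.06), of 12 regulatory T cell genes 8 (−0.17) and of 14 inhibitory checkpoint genes 9 (−0.19). With 1 library left out, these means ranged from −0.19 to 0.12, from −0.38 to −0.0045 and from −0.39 to −0.026. Of 22 helper T cell genes 11 were higher and 11 lower, with a mean of −0.0030 that was 0.018 after centring on housekeeping genes. They included Il12rb2, which encodes an interleukin 12 receptor chain (6.59 ± 0.78 and 5.79 ± 0.60, above background in 4 of 6 libraries, a difference of −0.80 that was −0.38 without vehicle 2), and Bcl6 (8.95 ± 0.27 and 9.49 ± 0.50, 0.54 apart but 0.26 without anti-CD40 1). Fry's adjusted p was 0.89 for the CD8, natural killer, regulatory T cell and checkpoint lists and 0.987 for helper T cells. Of 28 lymphoid chemokine and receptor genes 16 were lower (−0.12, 0.022 without anti-CD40 1, fry adjusted p = 0.89), yet the B cell chemoattractant gene Cxcl13 was 7.70 ± 0.52 and 9.12 ± 1.30, with groups that did not overlap and a difference of 1.42 that was 0.69 without anti-CD40 3.

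Myeloid lists were mixed, and in these 4 the sign of the mean turned without vehicle 3. Without anti-CD40 2 it also turned for macrophages (−0.0095), alternative activation (−0.050) and inflammatory cytokines (−0.12). Of 18 macrophage and monocyte genes 11 were higher (0.09 in the mean), with the scavenger receptor gene Cd163 at 7.90 ± 0.50 and 8.57 ± 0.37 and the mannose receptor gene Mrc1 at 9.27 ± 0.31 and 9.65 ± 0.15; without vehicle 3 these differences went from 0.67 to 0.39 and from 0.38 to 0.20. Both also stand in the list of alternative activation, in which 9 of 17 genes were higher (0.09). Of 28 inflammatory cytokine and chemokine genes 17 were higher (0.11). Ppbp, a chemokine gene of platelets, had the largest difference of all 770 genes, 2.24 (SE 0.90), but its groups overlapped at 7.48 ± 1.78 and 9.71 ± 1.03. Of 27 genes of Toll-like receptors and innate sensing 16 were higher (0.08), with Tlr7 at 6.22 ± 0.32 and 6.76 ± 0.13 and Cd180 at 7.66 ± 0.53 and 6.97 ± 0.33. Fry's adjusted p was 0.923 for alternative activation and 0.89 for the 3 others.

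Neutrophil and B cell genes varied more within groups than between them. Of 15 neutrophil genes 12 were higher, with a mean difference of 0.44 (fry adjusted p = 0.89) that ranged from −0.024 without vehicle 3 to 0.99 without vehicle 2. The list's mean was 7.32, 8.58 and 6.56 in vehicle libraries 1, 2 and 3, and 8.53, 8.41 and 6.84 in anti-CD40 libraries 1, 2 and 3. Granule genes of immature myeloid cells, several of which belong to the list, moved with it. The cathelicidin gene Camp was 4.27, 10.81 and 4.84 in the vehicle libraries and 11.17, 8.87 and 5.14 in the anti-CD40 libraries. Of 14 B cell genes 7 were higher and 7 lower (0.08, fry adjusted p = 0.981). That mean was 0.58 without vehicle 2 and −0.24 without vehicle 3. It was also negative without vehicle 1 (−0.11) and without anti-CD40 2 (−0.085). Vehicle 2 again had the highest list mean of its group, 6.94 beside 5.55 and 5.29. Only 1 of the 14 genes was above background in all 6 libraries. The background limit was 6.52 log2 in vehicle 2, beside 5.66 in vehicle 1 and 5.57 in vehicle 3. For members near background, part of this gap may thus come from scaling. The B cell, fibroblast and alternative activation lists, like the neutrophil and mast cell lists, had their 3 highest means in vehicle 2 and anti-CD40 1 and 2. For fibroblasts this ranking was narrow, with 10.32 in anti-CD40 1 beside 10.30 in anti-CD40 3. The fibroblast and alternative activation lists share Mmp9, which was called with Camp in the split between these libraries and the others (below). Without vehicle 2 and anti-CD40 1 and 2, the libraries with at least 5 of 6 granule genes above background, limma called 2 genes, Ppbp (4.10) and Cxcl13 (2.61). That fit left 2 vehicle libraries and 1 anti-CD40 library, which was assumed to vary like the others, and gave every gene the same standard error.

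**Figure D2:**
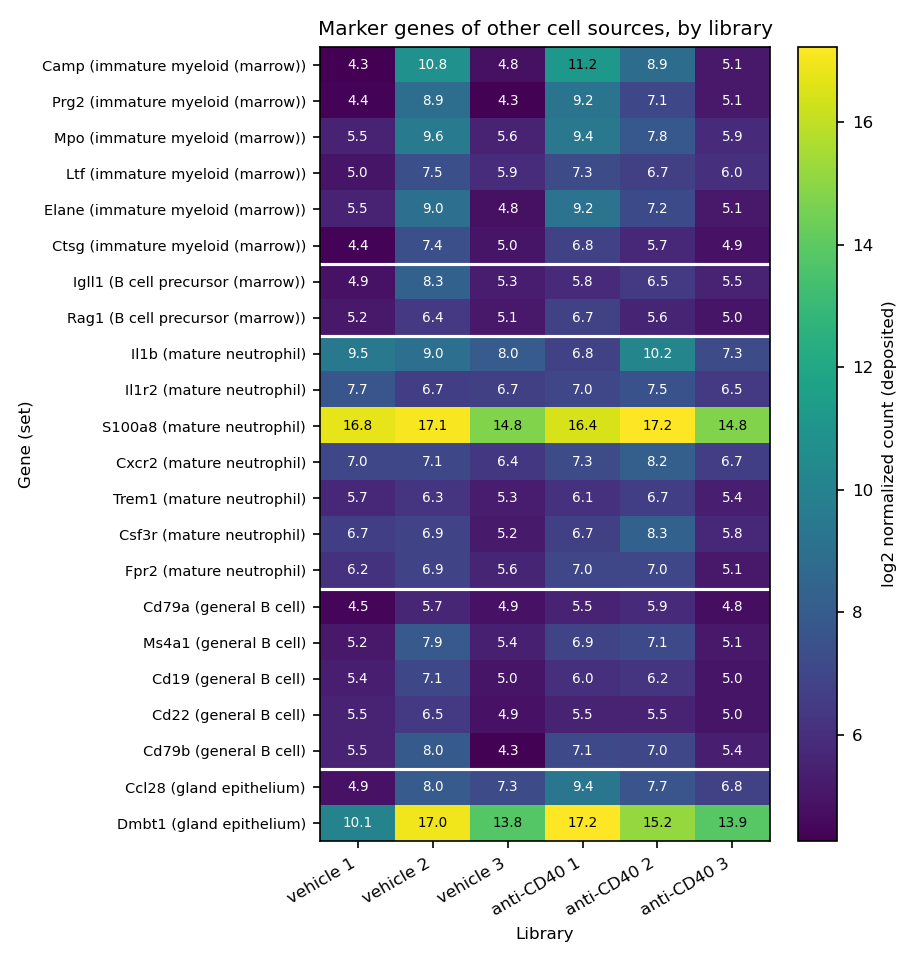
Log2 normalized counts (colour and printed value) of 22 marker genes of other cell sources (vertical axis) in each of the 6 libraries (horizontal axis), with white lines between marker sets. Granule genes such as Camp are high in vehicle 2 and anti-CD40 1 and 2 and low in the other libraries of both groups.

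Genes of tumour cells and of the cell cycle had small lists on this panel. Of 5 proliferation genes 4 were lower, with a mean difference of −0.34, between −0.44 and −0.23 with 1 library left out. These included Birc5 and the mitotic kinase gene Cdk1 (5.97 ± 0.21 and 5.17 ± 0.74, above background in only 2 of 6 libraries, a difference of −0.79 that was −0.39 without anti-CD40 1), whereas the cyclin gene Ccnd3 was 9.49 ± 0.37 and 9.89 ± 0.11 (0.40 apart, 0.23 without vehicle 1). Fry's adjusted p was 0.695, and this was the 1 list of 27 at an unadjusted p under 0.05. Of 8 epithelial genes 6 were lower (−0.22, −0.14 without anti-CD40 1, fry adjusted p = 0.695), including E-cadherin, Cdh1 (12.39 ± 0.13 and 12.03 ± 0.10), and the integrin gene Itga6 (12.72 ± 0.58 and 12.14 ± 0.65, a difference of −0.58 that was −0.25 without vehicle 3, −0.34 without anti-CD40 1 and −0.95 without anti-CD40 2). Of 15 apoptosis genes 10 were lower (−0.10, −0.049 without anti-CD40 3 and −0.17 without anti-CD40 2, fry adjusted p = 0.89), with the death receptor gene Fas at 7.93 ± 0.29 and 8.40 ± 0.30. Of 20 housekeeping genes 11 were higher and 9 lower, with a mean difference of −0.02 (fry adjusted p = 0.89). Their mean lay between 11.01 and 11.11 in every library. The deposited scaling may have leveled it, so the test on this list decides little. Birc5 was the only gene past the threshold in any list when adjusted over the list alone, in the proliferation list with an adjusted p of 0.0289, while over all genes none passed in any list.

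**Figure D3:**
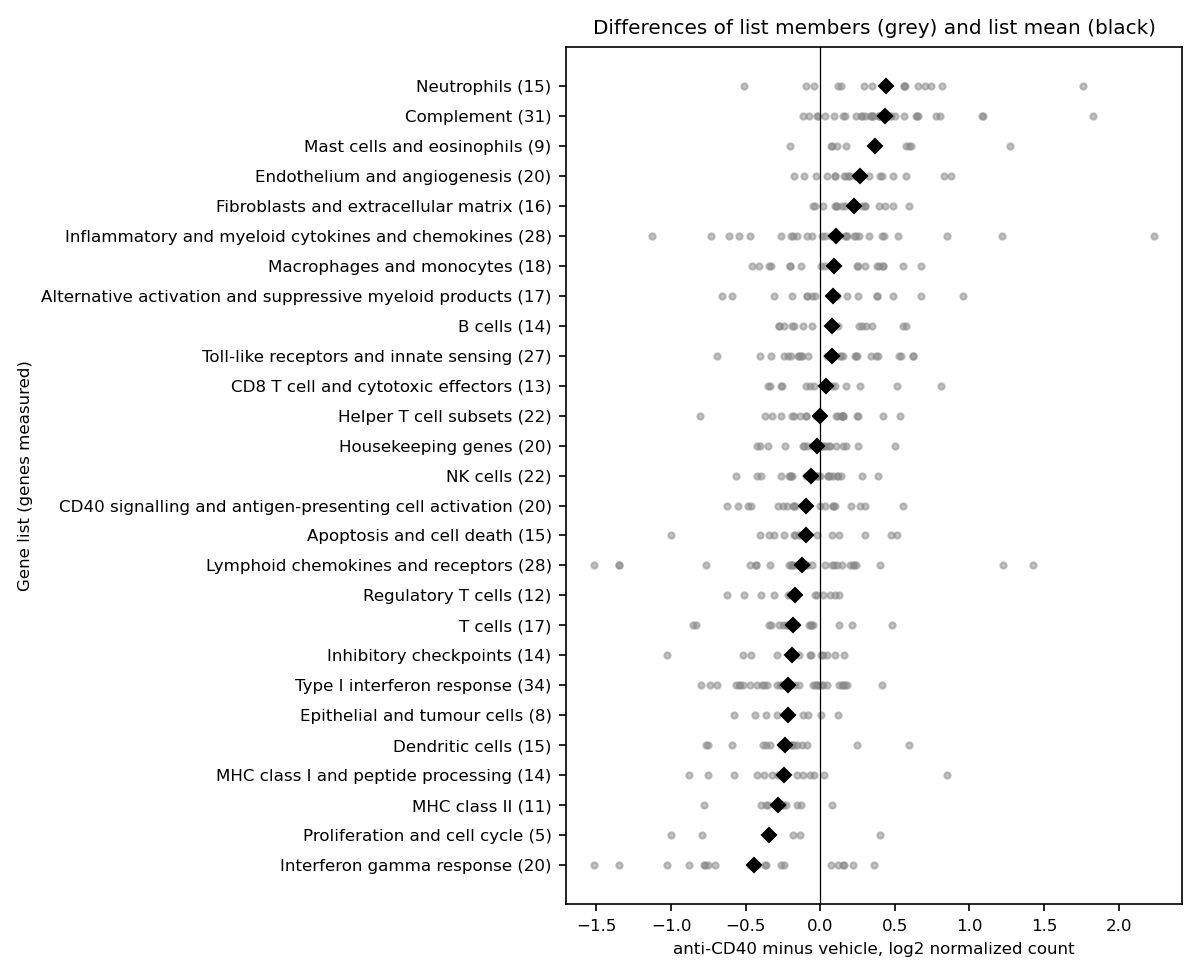
Difference between anti-CD40 and vehicle in log2 normalized count (horizontal axis) for each gene of the 27 tested lists (grey points), with the mean of the list as a black diamond; the number of genes measured stands beside the list's name (vertical axis). Neutrophil and complement genes have the highest list means and interferon gamma response genes the lowest, and none of the lists passed with fry.

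Leaving out 1 library moved the mean difference by over 1.5 times in 26 of the 27 lists and turned its sign in 12. It moved 47 of the 80 genes chosen by rule, Cd40 among them, as far. The limit is a ratio, so small moves pass it where the mean is near 0, as for housekeeping (−0.021) and helper T cell genes (−0.0030). For the complement, interferon gamma, epithelial and fibroblast lists, only 1 of the 6 libraries moved the mean that far. Camera called 9 lists at the preset correlation, 3 higher and 6 lower, and 0 with an estimated correlation, whereas fry called 0. In those 9 lists the estimated correlation lay between 0.092 for fibroblast genes and 0.65 for MHC class II genes, above the preset 0.01. The preset calls thus assume less correlation within a list than these data gave. The mean, the median and the direction of the test differed in sign for the housekeeping, CD8 and helper T cell lists. The median 95% confidence interval reached 0.71, or 1.64-fold, on either side of a gene's own estimated difference. A gene with an interval of this width and a smaller estimate could not be told from no change. With each library shifted to the same median, fry called the complement list (0.41, adjusted p = 0.0275) and the dendritic cell list (−0.25, adjusted p = 0.0241). Fry's adjusted p-values in the main fit were 0.695 and 0.89. Under other settings they reached 0.999 for both, a highest value that most lists share.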

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

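The settings chosen after seeing the data were limma-voom, the background filter, background subtraction, scaling to equal totals, the marrow covariate and leaving out the 3 libraries with high granule genes. Under every alternative but 1, limma called 0 of the genes it tested; the exception left out those 3 libraries and called 2, Ppbp and Cxcl13. The count of 25 at an unadjusted p under 0.05 (17 higher) was 42 (22 higher) after median centring, 52 (26 higher) after quantile normalization, 27 (21 higher) after housekeeping centring, 32 (18 higher) after scaling to equal totals, 42 (25 higher) with sample weights and 43 (22 higher) with background subtraction, and ranged from 13 to 49 with 1 replicate left out. It was 47 (40 higher) without vehicle 2, 43 (8 higher) without vehicle 3, 13 (10 higher) without anti-CD40 1 and 49 (18 higher) without anti-CD40 2. The median difference of all genes was 0.11 without vehicle 2 and −0.090 without vehicle 3. Fry's count of 0 lists became 2 after median centring and ranged from 0 to 1 with 1 replicate left out. The epithelial list passed fry without anti-CD40 2 (−0.30, adjusted p = 0.0246, against 0.695 in the main fit and up to 0.999 elsewhere). Camera called 9 at the preset correlation and 0 with an estimated correlation. The replicate number as a block gave 0 genes, 32 at an unadjusted p under 0.05 and 0 lists, so it changed no call. Deviations of same-numbered samples correlated at −0.43, 0.07 and 0.28 and not every sample correlated best with its own number, so the numbers were not read as pairs. Over all alternatives C5ar1 ranged from 0.95 to 1.21, Birc5 from −1.41 to −0.80 and the complement list from 0.28 to 0.59. Apart from the settings with 1 replicate left out, 2 values of single genes turned in sign and 1076 kept their direction and side of the threshold. Both turns of single genes came from leaving out the 3 libraries with high granule genes. For lists these counts were 19 and 353. The helper T cell list turned to 0.22 with the level filter, 0.0072 with the pseudocount, 0.018 with housekeeping centring, 0.021 with limma-voom, 0.0074 with the background filter and 0.11 without the 3 libraries. The CD8 list turned to −0.0016 with quantile normalization, −0.039 with sample weights, −0.25 with background subtraction and −0.0076 without the 3 libraries. The B cell list turned to −0.051 with sample weights, −0.22 with background subtraction and −0.16 with the marrow covariate. Alternative activation turned to −0.076 with sample weights, −0.038 with the marrow covariate and −0.15 without the 3 libraries. Inflammatory cytokines turned to −0.091 with background subtraction. Without the 3 libraries the natural killer list turned to 0.092, neutrophils to −0.10, Klrb1c to 0.11 and Cxcr2 to −0.0057. With 1 replicate left out, values that turned ranged from −0.48 to 0.028 for Cd40 (turned without anti-CD40 3), −0.035 to 0.47 for Cr2 and −0.018 to 0.65 for Fcer2a. For lists the ranges were −0.22 to 0.0036 for CD40 signalling, −0.24 to 0.58 for B cells, −0.12 to 0.15 for CD8, −0.19 to 0.12 for natural killer cells, −0.16 to 0.21 for helper T cells and −0.15 to 0.21 for macrophages. They were −0.14 to 0.31 for alternative activation, −0.024 to 0.99 for neutrophils, −0.46 to 0.00060 for type I interferon, −0.29 to 0.022 for lymphoid chemokines, −0.12 to 0.30 for inflammatory cytokines and −0.038 to 0.17 for innate sensing. The cause of these turns was not tested. Leaving out 1 library moved 26 of the 27 list means by over 1.5 times, all but proliferation, and 47 of the 80 genes chosen by rule, Cd40 among them. Small moves pass this ratio where the mean is near 0, as for housekeeping and helper T cell genes. Background subtraction put Fcer2a and Fasl at the floor, so they showed no difference there and were left out of the counts of kept and turned values. The filters left lists with under 3 genes untested. Counts near the negative controls limit lists such as CD8 (0 of 13 genes above background in all libraries) and B cells (1 of 14).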

Other observations

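The marker sets of cell sources, the tests on them and the counts over other splits of the libraries were all chosen after the values had been seen. Dmbt1 and Ccl28, genes of glandular epithelium, varied widely within both groups. Both were highest in vehicle 2 and anti-CD40 1 and 2, the libraries with high granule genes. Ccl28 was 7.99, 9.37 and 7.66 there, beside 4.92, 7.28 and 6.83 in vehicle 1, vehicle 3 and anti-CD40 3. What links gland and granule genes was not tested. Dmbt1 was 10.06, 16.96 and 13.83 in vehicle libraries 1, 2 and 3 and 17.23, 15.17 and 13.89 in anti-CD40 libraries 1, 2 and 3, and in anti-CD40 1 it took 13.5% of all gene counts. The mean of both genes differed by 1.52 between groups (exact permutation p = 0.5). Platelet and megakaryocyte genes (Ppbp, Itga2b and Itgb3) had a mean of 7.38 ± 1.02 in vehicle and 8.56 ± 0.69 in anti-CD40 tumours (exact permutation p = 0.2), with Ppbp at 38, 221 and 58 counts in the vehicle and 450, 153 and 539 counts in the anti-CD40 libraries. Mature neutrophil genes differed by 0.11 (exact permutation p = 1), general B cell genes by 0.17 (p = 0.9 by the same exact test) and the B cell precursor genes Igll1 and Rag1 by −0.002 (exact p = 1).

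The mean of 6 granule genes of immature myeloid cells (Camp, Prg2, Mpo, Ltf, Elane and Ctsg) was 4.86, 8.87 and 5.08 in vehicle libraries 1, 2 and 3 and 8.85, 7.25 and 5.37 in anti-CD40 libraries 1, 2 and 3. Unequal scaling is argued against, since the recovered counts varied by a median of 4.16 log2 beside 0.93 for the factors, and so are mature neutrophils alone, since granule genes varied by 4.31 log2 relative to mature neutrophil genes, beyond the 1.55 of the most variable housekeeping gene. Bone marrow near the tumour may be a source and stays open: 1 of the B cell precursor genes Igll1 and Rag1 was above background in each of the 3 libraries with high granule genes and in no other, but no library had both, so that with a criterion asking for both, precursor and granule genes matched in 3 of 6 libraries, those low in both. As first set, that criterion counted against marrow, and it was relaxed after the result was seen; Igll1 reached 95 counts in vehicle 2, beside a background limit of 26.6. An effect of anti-CD40 on granule genes cannot be told apart from variation between tumours (exact permutation p = 0.6, with a lowest possible value of 0.1).

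Over the 10 splits of the 6 libraries into 3 and 3, a comparison of calls decides nothing, because the real split called 0 genes and 0 lists and all 10 reach that by construction; the highest other splits called 9 genes and 3 lists. At an unadjusted p under 0.05, 7 of the 10 splits gave at least the 25 genes of the real one, and the highest other gave 111. With 10 splits, no share under 0.05 can be reached. The split that set vehicle 1, vehicle 3 and anti-CD40 3 against the rest called Camp, Prg2, Pou2af1, Mmp9, Mpo, Ms4a1, Cfd, Elane and Cd79b. The split that set vehicle 1, vehicle 2 and anti-CD40 2 against the rest gave the 111 genes, several times the real 25, and called the T cell, dendritic cell and lymphoid chemokine lists. It was picked as the highest of the 10, and this maximum was not set against what chance gives. The groups overlapped on principal components 1 and 2, which held 43.0% and 25.1% of the variance. On the first, vehicle 2 and anti-CD40 1 and 2 lay at 10.8, 10.2 and 4.27. Vehicle 1, vehicle 3 and anti-CD40 3 lay at −10.9, −9.04 and −5.29. On the second, vehicle 1, vehicle 2 and anti-CD40 2 lay at −7.45, −5.75 and −6.70, beside positive values in the other libraries. These partings match the splits just described, but both come from the same values. What lies behind them is a hypothesis only.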
